A study of Rattus norvegicus with 12 samples.

How the data were processed

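Total RNA from 12 cultures of ventricular cardiomyocytes of newborn rats was labelled with Cy3 and hybridised to Agilent rat gene expression arrays, 1 culture per array. Per the labels, the 4 groups were unstretched controls and cells under pulsatile stretch for 2, 6 or 24 h, each with 3 biological replicates. The array design files place the probes on rat genome build rn4. Per the file headers the scanner images were read with Agilent Feature Extraction 11.0.1.1, while the submitters' processing notes name version 10.7.3.1. Per the file headers, the processed signal is an intensity on a linear scale, with background subtracted and spatial trends removed within the array and with no scaling between arrays. The mean signal and the local background in the same files are intensity values without subtraction, and the spot flags are other values, 0 or 1, per the file headers. The deposited series matrix holds an intensity on a linear scale for 28902 probes in 12 columns, all of which were used; its ranks followed the mean signal of the same array with a rank correlation of at least 0.9988, and its column medians on the log2 scale lay between 7.02 and 7.14. How that matrix was scaled between arrays is not stated, so it served only as an alternative.

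The processed signal was put on the log2 scale, spots marked as outliers by the image software were left out (224 to 359 of 58717 per array), and spots of 1 probe were averaged. From each array its 75th percentile was subtracted. A probe was kept when it was marked as well above background on all 3 arrays of at least 1 group, which left 18997 of 30367 probes. Probes were named through their accession (18005), the symbol in the file (2668) or a synonym with a single current gene (547), and 4963 kept the name in the file; the remaining 4184 had no gene name. Of the kept probes 16961 had a name and 2036 had none and were tested apart. For each of 14376 genes the probe with the highest mean signal was used; 2349 genes had more than 1 kept probe, and of the 1150 such genes called at 24 h, 147 (12.8%) had a further probe with a change of the other sign. Where no array of a group was above background for a gene, its fold is given as a bound on the processed signal, computed with each dim value raised to the lowest signal that counted as above background on that array. Where the dim values already lay above that signal, this equals the fitted fold, which is given as such and not as a bound, and normexp and the series matrix gave smaller changes for these genes.

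A linear model with a mean for each of the 4 groups was fitted to all 12 arrays with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with jsonlite 2.0.0, statmod 1.5.0 and the package data.table (version 1.17.8). The 6 differences between groups and a moderated F test over all groups were adjusted by the Benjamini-Hochberg method over the genes tested, and a gene was called at an adjusted p below 0.05. All tests were two-sided. Errors given with log2 changes are standard errors of the model, with n = 3 arrays per group.

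The gene lists, the rule for the genes to be named and the planned tests were chosen before the data were examined; tests and alternatives chosen later are given as such. The 34 lists, with 797 distinct genes of which 719 were tested, covered immediate-early genes, hypertrophy and stretch markers, sarcomere genes, calcium handling, ion channels and gap junctions, beta-adrenergic and G-protein receptor signalling, YAP/TAZ targets, actin cytoskeleton, extracellular matrix, cytokines and NF-kB targets, interferon-stimulated genes, NRF2 and oxidative-stress genes, unfolded protein and integrated stress response, heat-shock and chaperone genes, fatty-acid oxidation, glycolysis, oxidative phosphorylation, cell cycle, p53 targets, cholesterol synthesis, circadian clock, MAPK feedback, growth factors, TGF-beta and SMAD targets, protein degradation, ribosome biogenesis and cardiac transcription factors. Another 7 lists held markers of fibroblasts, endothelial cells, smooth muscle and pericytes, macrophages and leukocytes, epicardial and mesothelial cells, neural and Schwann cells, and red blood cells; they count among the 34. A list needed 5 tested members, and the red blood cell list, with 3 of its 9, was not tested. The extracellular matrix and fibroblast lists share 6 tested genes, actin and smooth muscle share 2, and no other pair shares more than 1. Lists were tested against all other genes with limma's camera at a preset correlation of 0.01, adjusted over the 33 lists and the 3 comparisons with the control, and again with the correlation estimated from the data. Counts of members are given over all genes tested and as adjusted over the list alone.

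Named genes were 12 fixed in advance, the 10 rising and 10 falling genes with the largest called change and no overlap between groups at each time, up to 4 called members of each list with the largest change, and 5 rising and 5 falling genes for 6 h against 2 h and for 24 h against 6 h; only genes with a true symbol were taken, and some were left out of the text or are not reported here.

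The arrays lay on 2 slides, each with its own scan, so scan and slide are the same factor. Alternatives tried were quantile normalization, each array's median as the scale, normexp background correction with an offset of 50, the series matrix, spike-in scaling, no probe filter, probes above background on all 12 arrays, the mean of a gene's probes, a trended and robust prior, slide as a fixed or random block, each slide alone, replicate numbers as a block, each array left out in turn, only the arrays compared, a minimum change of 2-fold, and the directional set test fry. The model was tested on simulated data with 50 altered genes at each of 4 sizes: of the altered genes it called 84% at a log2 change of 0.5, 94% at 1, 98% at 1.5 and 100% at 2, and 10 of 198 calls (5.05%) were of unaltered genes. The simulated noise was normal and independent between genes, with no slide difference or scaling error. The 5.05% is therefore no false-call rate of the real calls. With 12 arrays the number of arrays limits the precision of every value. Each range of adjusted p runs over unlike alternatives, so its lower end comes from the most favourable of them and does not measure the evidence. No genome sequence was used, and probes were not realigned.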

Results

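Gene expression was compared between unstretched ventricular cardiomyocytes of newborn rats and the same cell type under pulsatile stretch along both axes with 20% elongation for 2, 6 or 24 h. The cells had been cultured for 24 h with 10% serum on flexible collagen-coated plates. Each of the 4 groups had 3 cultures, which the labels call biological replicates, and each culture was read on 1 array; whether these are separate cell isolations is not given in the sources used here, so n = 3 and every error refer to cultures and not to isolations. The same 3 control cultures served all 3 stretch times, and the labels name no culture time for them. No change here, against control or between times, was separated from time in culture. The 75th percentile of the processed intensity lay between 1142 and 1671 on the 12 arrays, between 64.7% and 70.6% of 58717 spots were well above background, and 0 spots were saturated.

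The arrays fell into their groups on the first 2 principal components, which held 54.0% and 10.7% of the variance. Across genes, which are not independent replicates, Pearson's r was 0.996 to 0.998 in the 12 pairs of arrays from 1 group and 0.987 to 0.996 in the 54 pairs from different groups. The 3 control arrays, the 3 arrays of 2 h and 2 arrays of 6 h lay on slide 1 (8 arrays), and the remaining 6 h array and the 3 arrays of 24 h lay on slide 2 (4 arrays), so only the 6 h group ties both slides together. Of 14376 genes tested, 7597 (52.8%) differed among the 4 groups by the moderated F test of limma, and with slide as a block 2798 did.

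**Figure D1:**
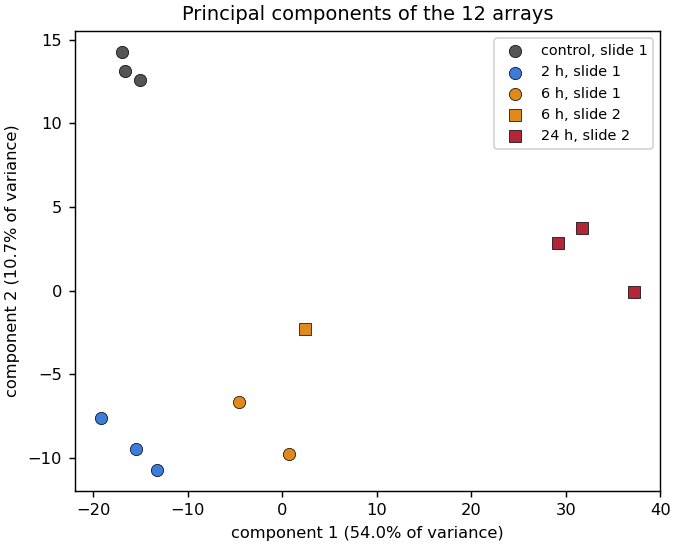
Scores of the 12 arrays on the first 2 principal components of the scaled log2 values, which hold 54.0% and 10.7% of the variance; colours mark the group, circles slide 1 and squares slide 2. The 24 h arrays lie apart from the other 9 along the first component.

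All changes are relative to the 75th percentile of each array. On that scale the median of all genes moved by -0.01 at 2 h, -0.05 at 6 h and -0.08 at 24 h; scaled by the array median it moved by 0.11 at 24 h, and scaled by the spike-in spots by 0.17, 0.43 and 0.35 at the 3 times. The split into higher and lower genes depends on this choice and is given under several scalings for each time. None of the 43 list results described here kept its call with an estimated correlation (0 of 99 camera tests, 20 of them with an unadjusted p under 0.05; the directional test fry called 59 of 99, of which 38 were among the 43). Replacing dim values by their bounds moved no list median. Median, mean and test direction differed in sign for 0 of the 43 called lists and for 22 of the other 56.

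The first comparison takes 2 h. Immediate-early and heat-shock lists were higher after 2 h of stretch. Atf3, a stress-induced transcription factor (chromosome 13, 107191691 to 107191749 on rat genome build rn4), rose 2.24-fold (log2 change 1.16 ± 0.11, SE, n = 3 per group, adjusted p = 7.66e-04). Gjb2, which encodes a gap junction protein, rose 2.19-fold (1.13 ± 0.10), and Hspa1b, an inducible heat-shock protein of the Hsp70 family, rose 1.93-fold (0.95 ± 0.12). The natriuretic peptide gene Nppb, a marker of cardiomyocyte load (chromosome 5, 165062879 to 165062938), rose 1.36-fold (0.45 ± 0.08), while the related Nppa changed by -0.17 ± 0.06 with an adjusted p of 0.112. In all, 1322 genes were called at 2 h, 445 higher and 877 lower (9.20% of those tested), and 15 of them changed at least 2-fold.

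Of 27 immediate-early genes measured at 2 h, 15 rose, 1 fell and 11 were not called (17 and 3 adjusted over the list alone), with a median change of 0.26 (camera adjusted p = 3.45e-08, and adjusted p = 0.0985 with an estimated correlation). Fos, a subunit of the AP-1 transcription factor, rose by 0.60 ± 0.11, whereas Egr1 changed by 0.19 with an adjusted p of 0.292. Heat-shock and chaperone genes had 9 risers, 0 fallers and 12 uncalled members (12 and 0 adjusted over the list alone). The heat-shock median was 0.16 (adjusted p = 3.84e-08, and adjusted p = 0.169 with an estimated correlation). Among them the co-chaperones Dnajb1 and Bag3 rose by 0.50 and 0.49. Hypertrophy and stretch markers had 10 risers, 0 fallers and 13 uncalled (13 and 1 adjusted over the list alone). The hypertrophy median was 0.14 (adjusted p = 1.43e-07, and adjusted p = 0.0693 with an estimated correlation). In that list Tnfrsf12a, the receptor of the cytokine TWEAK, rose by 0.75, Rcan1, a calcineurin regulator and calcineurin target (chromosome 11, 32386621 to 32386680), by 0.45 ± 0.07, and Ankrd1, a stretch-responsive sarcomere-associated protein, by 0.32. The myosin heavy chains Myh6 (0.14, adjusted p = 0.264) and Myh7 (0.08, adjusted p = 0.499) and the calcium pump Atp2a2 (0.01, adjusted p = 0.955) were not called. Skeletal actin Acta1 rose by 0.30 (adjusted p = 0.022); that call ended without control replicate 1 (adjusted p = 0.065), control replicate 2 (0.0811), 2 h replicate 1 (0.0728) or 2 h replicate 2 (0.0623), and its adjusted p ranged from 0.00433 to 0.357 over the alternatives.

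The cholesterol synthesis and cell cycle lists were lower at 2 h relative to other genes, with medians above 0 under spike-in scaling, where the cholesterol list passed the set test (adjusted p = 0.0139) and the cell cycle list did not (0.0803, range 2.78e-06 to 0.364). As that scaling shifts all genes of an array alike, the pass is no independent support. Cholesterol synthesis genes had 0 risers, 8 fallers and 14 uncalled (0 and 11 adjusted over the list alone). The cholesterol median was -0.17, and 0.01 with spike-in scaling (adjusted p = 1.44e-06, and adjusted p = 0.0693 with an estimated correlation), and Dhcr7, the last enzyme of the pathway, fell by 0.40. Of 33 cell cycle genes 1 rose, 10 fell and 22 were not called (1 and 15 adjusted over the list alone). The cell cycle median was -0.12, and 0.06 with spike-in scaling (adjusted p = 4.76e-04, and adjusted p = 0.364 with an estimated correlation), including the kinetochore protein Cenpf (-0.37) and the spindle motor Kif11 (-0.33). Fatty-acid oxidation genes had 7 risers, 1 faller and 23 uncalled (9 and 1 adjusted over the list alone). The fatty-acid oxidation median was 0.11 (adjusted p = 2.42e-05, and adjusted p = 0.364 with an estimated correlation). NRF2 and oxidative-stress genes had 3 risers, 0 fallers and 20 uncalled (4 and 0 adjusted over the list alone). The NRF2 median was 0.11 (adjusted p = 2.14e-04, and adjusted p = 0.364 with an estimated correlation). Hmox1, which encodes the haem-degrading enzyme haem oxygenase 1 (chromosome 19, 13969336 to 13969395), rose by 0.73 ± 0.13 and Osgin1 by 0.60.

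Macrophage and leukocyte markers were slightly higher at 2 h. Of 12 measured, 2 rose, 0 fell and 10 were not called (2 and 0 adjusted over the list alone). The macrophage median was 0.12 (adjusted p = 0.00349, and adjusted p = 0.364 with an estimated correlation), and the macrophage surface marker Adgre1 rose by 0.59. Interferon-stimulated genes had 0 risers, 4 fallers and 16 uncalled (0 and 4 adjusted over the list alone). The interferon median was -0.10, and 0.08 with spike-in scaling (adjusted p = 0.0419, and adjusted p = 0.364 with an estimated correlation). This set call ended without control replicate 1 (adjusted p = 0.169), 2 h replicate 1 (0.0529) or 2 h replicate 3 (0.153), with quantile normalization (0.0853) and with spike-in scaling (0.336), with a range of 0.00621 to 0.364 over the alternatives. The cytokine Tnf fell by 0.53 (adjusted p = 0.0326). Spic, a transcription factor of iron-recycling macrophages, was by the fit 3.78-fold lower, a value that is no bound, with 0 of 3 arrays at 2 h above background, and its change was -0.90 with normexp and with the series matrix. The Tnf call ended without any 1 of control replicates 1 to 3 (adjusted p = 0.0968, 0.0789 and 0.0585) or 2 h replicates 1 and 2 (0.0994 and 0.096), with a range of 0.00375 to 0.649. The Spic call ended without control replicate 1 (0.098), control replicate 2 (0.109) or any 1 of 2 h replicates 1 to 3 (0.0848, 0.0884 and 0.0738), with a range of 1.9e-14 to 0.109. Zc3h12d, which encodes an RNA-binding protein of the family that limits inflammation, was by the fit 2.39-fold lower, again no bound and with 0 of 3 arrays at 2 h above background, and its change was -0.50 with normexp and -0.46 with the series matrix.

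The 2 h calls came from limma. Their number fell to 665 without control replicate 2, 735 without control replicate 3 and 812 without 2 h replicate 1, and it was 463 when only the 6 arrays compared were fitted. All 6 arrays lay on slide 1; with that slide alone 813 genes were called, 24 of the 26 called named genes kept their call (Acta1 and Spic did not) and 16 of 16 lists did. The Ankrd1 call ended with quantile normalization (0.25, adjusted p = 0.0704), with only the 2 groups fitted (0.0567) and with spike-in scaling (0.307), with a range of 0.00172 to 0.307. Acta1 lost its call with quantile normalization (0.0564), slide 1 alone (0.0538), no filter (0.0584), only the 2 groups (0.0866) and spike-in scaling (0.357). Without a filter and with only the 2 groups Spic (0.0816 and 0.0825) and Tnf (0.0777 and 0.063) were not called, nor was Spic on slide 1 alone (0.0582). Spike-in scaling also ended the calls of Nppb (0.63, adjusted p = 0.0905), Rcan1 (0.63, 0.0905), Bag3 (0.67, 0.0577), Dnajb1 (0.67, 0.0523), Cenpf (-0.19, 0.667), Kif11 (-0.15, 0.71), Dhcr7 (-0.22, 0.649) and Tnf (-0.36, 0.649), whose adjusted p over the alternatives reached as low as 2.39e-04 and as high as 0.71. Of the called genes 66.3% were lower, against 63.1% with quantile normalization, 47.0% with array medians (668 higher and 593 lower), 59.8% with normexp, 66.3% with the series matrix and 27.2% with spike-in scaling (126 and 47). The groups did not overlap for 28.6% of genes, where chance gives 10%.

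The second comparison takes the middle time, 6 h. After 6 h, the cytokine and interferon-stimulated lists were lower relative to other genes, while ribosome biogenesis genes and hypertrophy markers were higher. With spike-in scaling the cytokine and interferon medians lay above 0. Both lists passed the camera set test there (adjusted p = 4.08e-06 and 2.95e-07). As said, this is no independent support. The cytokine Tnf (chromosome 20, 3663558 to 3663617) fell 2.76-fold (-1.46 ± 0.13, n = 3 per group, adjusted p = 4.12e-04), and the chemokine Ccl3 fell by 1.37 ± 0.11. Il1rl1, the receptor of interleukin 33, rose 2.02-fold (1.01 ± 0.09) and Nppb rose 1.68-fold (0.75 ± 0.08). At 6 h 2408 genes were called, 728 higher and 1680 lower (16.8% of those tested), and 30 changed at least 2-fold.

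Of 20 interferon-stimulated genes 0 rose, 12 fell and 8 were not called (0 and 14 adjusted over the list alone), with a median of -0.40, and of -0.43 with slide as a block, but of 0.09 with spike-in scaling (adjusted p = 8.94e-06, and adjusted p = 0.0917 with an estimated correlation). Usp18, a negative regulator of interferon signalling, fell by 0.92, and the transcription factor Irf7 fell by 0.50, a call that ended without 6 h replicate 1 (adjusted p = 0.0565, range 0.00392 to 0.953). Cytokines and NF-kB targets had 2 risers, 11 fallers and 16 uncalled (2 and 13 adjusted over the list alone). The cytokine median was -0.25, -0.29 with slide as a block and 0.23 with spike-in scaling (adjusted p = 0.0204, and adjusted p = 0.411 with an estimated correlation). Il1b fell by 0.72, and Il1a fell by 1.75 with 1 of 3 arrays at 6 h above background (by 0.59 with normexp and 0.48 with the series matrix). Macrophage and leukocyte markers had 0 risers, 2 fallers and 10 uncalled (0 and 4 adjusted over the list alone), with a median of -0.15, or -0.13 with slide as a block, or 0.33 with spike-in scaling, and did not pass the set test (adjusted p = 0.0725). Their member Ptprc, the leukocyte common antigen CD45, fell by 0.42, but was 0.06 higher with spike-in scaling. Spic was by the fit 4.82-fold lower, which is no bound, with 0 of 3 arrays at 6 h above background (-0.99 with normexp and -0.95 with the series matrix).

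Ribosome biogenesis genes had 13 risers, 0 fallers and 10 uncalled at 6 h (17 and 0 adjusted over the list alone). The ribosome biogenesis median was 0.22, 0.19 with slide as a block (adjusted p = 1.27e-10, and adjusted p = 0.085 with an estimated correlation), among them Heatr1 (0.40), nucleostemin Gnl3 (0.36) and Bop1 (0.29), which act in ribosome assembly in the nucleolus. Hypertrophy and stretch markers had 12 risers, 0 fallers and 11 uncalled (14 and 1 adjusted over the list alone). The hypertrophy median was 0.34, 0.33 with slide as a block (adjusted p = 3.83e-10, and adjusted p = 0.0693 with an estimated correlation). Xirp2, an actin-binding protein of the intercalated disc, rose by 0.78, Tnfrsf12a by 0.69, Acta1 by 0.60, Rcan1 by 0.55 and Ankrd1 by 0.40. Nppa (-0.08, adjusted p = 0.373), Myh6 (-0.07, adjusted p = 0.513), Myh7 (-0.13, adjusted p = 0.188) and Atp2a2 (-0.05, adjusted p = 0.654, and 0.18 on its other probe) were not called. Heat-shock and chaperone genes had 9 risers, 0 fallers and 12 uncalled (14 and 0 adjusted over the list alone). The heat-shock median was 0.17, 0.15 with slide as a block (adjusted p = 3.35e-09, and adjusted p = 0.151 with an estimated correlation), with Hsph1 at 0.61 and Chordc1 at 0.47.

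Immediate-early genes had 10 risers, 3 fallers and 14 uncalled at 6 h (11 and 4 adjusted over the list alone). The immediate-early median was 0.14 with or without slide as a block (adjusted p = 3.4e-04, and adjusted p = 0.261 with an estimated correlation). Atf3 rose by 1.01 and Fosl1, another AP-1 subunit, by 0.75, whereas Fos changed by 0.17 (adjusted p = 0.331) and Egr1 by -0.15 (adjusted p = 0.350). Cholesterol synthesis genes had 0 risers, 10 fallers and 12 uncalled (0 and 15 adjusted over the list alone). The cholesterol median was -0.16, -0.18 with slide as a block and 0.32 with spike-in scaling (adjusted p = 2.42e-05, and adjusted p = 0.0693 with an estimated correlation). Dhcr7 fell by 0.47, but was 0.01 higher with spike-in scaling. NRF2 and oxidative-stress genes had 7 risers, 0 fallers and 16 uncalled (8 and 0 adjusted over the list alone). The NRF2 median was 0.06, 0.09 with slide as a block (adjusted p = 0.00106, and adjusted p = 0.379 with an estimated correlation). By fry the list was not called (adjusted p = 0.0806, range 4.07e-05 to 0.379). Hmox1 rose by 0.84, Srxn1 by 0.58 and Osgin1 by 0.49. The unfolded protein and integrated stress response list had 5 risers, 1 faller and 24 uncalled (5 and 1 adjusted over the list alone). The unfolded protein median was 0.00 (adjusted p = 0.0259, and adjusted p = 0.419 with an estimated correlation), a call that ended with quantile normalization (0.123), by fry (0.261), with slide as a block (median -0.03, adjusted p = 0.19), on slide 1 alone (-0.03, 0.231) and without 6 h replicate 3 (-0.03, 0.194), with a range of 0.00115 to 0.419. Gjb2 rose by 1.02, the connective tissue growth factor gene Ccn2 by 0.34 and Duox2, which encodes an enzyme that makes hydrogen peroxide, by 1.00. The ion channel genes Scn4b and Kcnq1 fell by 0.91 and 0.61. The Duox2 call ended with normexp (adjusted p = 0.102, range 1.01e-10 to 0.102) and the Ccn2 call on slide 1 alone (0.0569, range 9.36e-04 to 0.0569).

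The 6 h calls came from limma. With slide as a block 1600 genes were called, 1494 of them among the 2408. The named genes, picked as said, kept 31 of 31 calls and the lists 8 of 9. For 6 h against control or 2 h the block acts like leaving out 6 h replicate 3, the only array of that time on slide 2. The 2 are no separate checks. On slide 1 alone, with 2 arrays at 6 h, 1350 genes were called. Spike-in scaling ended the calls of Scn4b (-0.43, adjusted p = 0.0575), Kcnq1 (-0.12, 0.567), Il1b (-0.24, 0.271), Usp18 (-0.44, 0.0544) and Irf7 (-0.01, 0.953), and those of Dhcr7 (0.01, 0.948) and Ptprc (0.06, 0.77), which changed sign; over the alternatives the adjusted p of these 7 reached as low as 1.97e-06 and as high as 0.953. Their number was 1537 without control replicate 2, 1478 without control replicate 3, 1195 without 6 h replicate 1 and 1600 without 6 h replicate 3. Of the called genes 69.8% were lower, against 49.4% with quantile normalization (1064 higher and 1040 lower), 26.3% with array medians (2074 and 742), 53.2% with normexp (978 and 1113), 59.9% with the series matrix and 0.687% with spike-in scaling (6646 and 46). The groups did not overlap for 39.4% of genes, against 10% by chance.

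**Figure D2:**
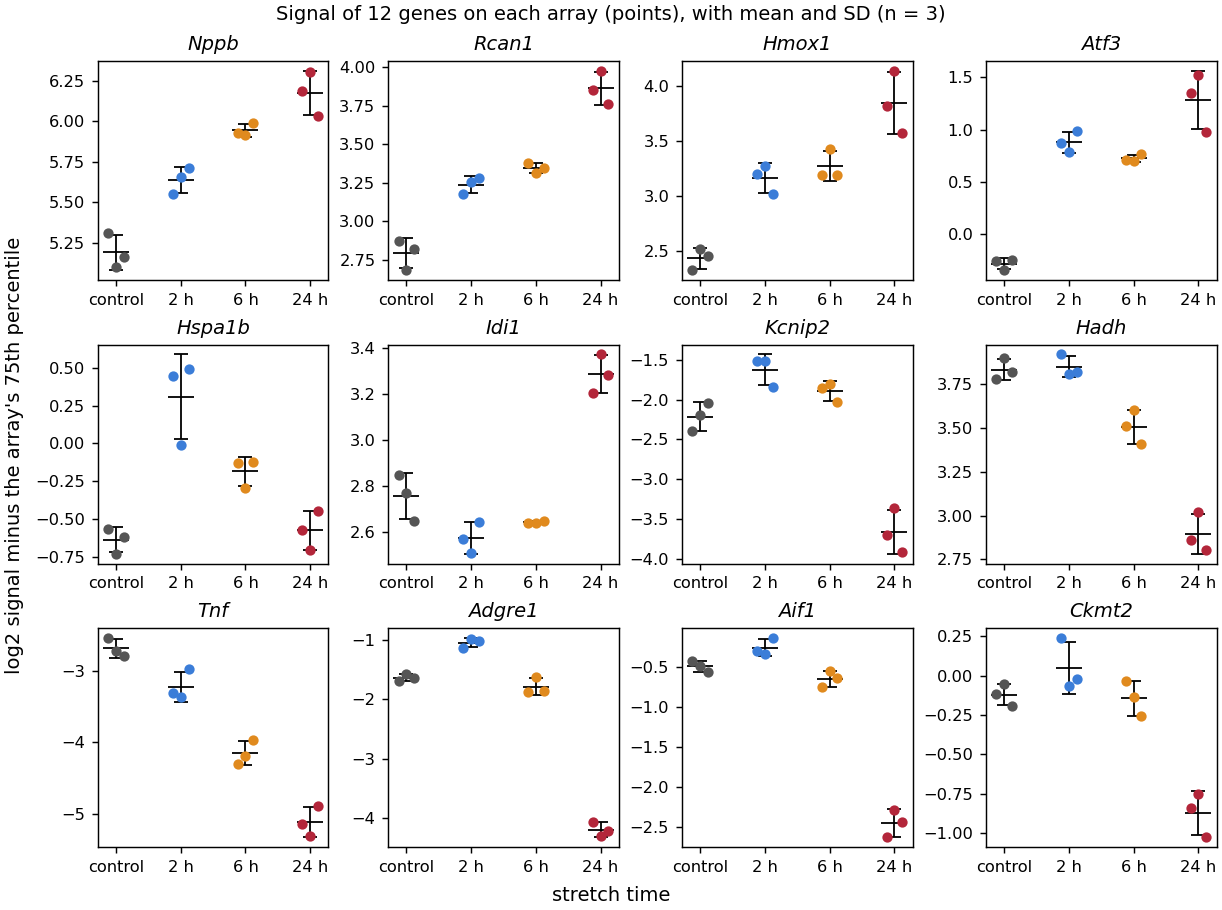
Log2 intensity relative to the array's 75th percentile for 12 genes in unstretched cells and after 2, 6 and 24 h of stretch; points are single arrays (n = 3 per group) and bars give the mean and SD. Nppb and Rcan1 were above the control at each time, Hspa1b was highest at 2 h, and Tnf, Adgre1 and Aif1 were lowest at 24 h.

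The third comparison takes the longest stretch, 24 h. Macrophage and leukocyte markers, ion channel genes and genes of fatty-acid oxidation were lower at 24 h, while hypertrophy markers and ribosome biogenesis genes were higher. Under spike-in scaling the fatty-acid oxidation median lay above 0 and the list passed the camera set test (adjusted p = 0.00714). As said, that pass is no independent support. Nppb rose 1.98-fold (0.98 ± 0.08, n = 3 per group, adjusted p = 5.46e-06) and Nppa 1.62-fold (0.69 ± 0.06). Stmn4, which encodes a microtubule-destabilising protein of the stathmin family (chromosome 15, 45794337 to 45794396), rose 8.42-fold (3.07 ± 0.22), and Gdf15, a stress-induced secreted factor, rose 3.14-fold (1.65 ± 0.12). Adgre1 fell 5.94-fold (-2.57 ± 0.08). At 24 h 6888 genes were called, 2324 higher and 4564 lower (47.9% of those tested), and 486 changed at least 2-fold, 80 higher and 406 lower.

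All 12 macrophage and leukocyte markers measured fell at 24 h (0 and 12 adjusted over the list alone), with a median of -1.37, and of -1.40 with slide as a block (adjusted p = 1.8e-09, and adjusted p = 0.0693 with an estimated correlation). C1qa, a complement component made by macrophages, fell by 2.49, Aif1 by 1.96 and Ptprc by 1.57. In the processed signal Spic was at least 7.92-fold lower and the class II antigen gene RT1-Bb at least 6.46-fold lower, each with 0 of 3 arrays at 24 h above background, and the class II invariant chain Cd74 fell by 2.80, with 1 of 3 arrays above background. With normexp and the series matrix these changes were smaller: -1.27 and -0.97 for Spic, -1.08 and -0.87 for RT1-Bb and -1.33 and -1.22 for Cd74. Interferon-stimulated genes had 3 risers, 12 fallers and 5 uncalled (3 and 14 adjusted over the list alone). The interferon median was -0.43, -0.46 with slide as a block and 0.01 with spike-in scaling (adjusted p = 0.023, and adjusted p = 0.364 with an estimated correlation), including Usp18 (-1.28) and Irf7 (-1.04); without control replicate 1 this set call ended (adjusted p = 0.0631, range 3.53e-05 to 0.364). Cytokines and NF-kB targets went both ways at 24 h, with 10 risers, 13 fallers and 6 uncalled (10 and 13 adjusted over the list alone), and did not pass (median -0.07, 0.13 with array medians and 0.36 with spike-in scaling; adjusted p = 0.893): Tnf fell by 2.43 and Il1b by 1.75, and Il1rl1 rose by 1.23.

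Endothelial markers had 1 riser, 9 fallers and 3 uncalled (1 and 9 adjusted over the list alone). The endothelial median was -0.49, -0.41 with slide as a block (adjusted p = 0.0303, and adjusted p = 0.256 with an estimated correlation), with the vascular growth factor receptor Flt1 at -0.77 and the endothelial cadherin Cdh5 at -0.64. Fibroblast markers had 0 risers, 10 fallers and 5 uncalled (1 and 10 adjusted over the list alone). The fibroblast median was -0.32, -0.30 with slide as a block and 0.11 with spike-in scaling (adjusted p = 0.0344, and adjusted p = 0.419 with an estimated correlation), with Thy1 at -0.79. The endothelial set call ended with slide as a block (adjusted p = 0.0735), with quantile normalization (median -0.25, 0.0739), with spike-in scaling (-0.06, 0.0503) and without control replicate 1 (0.0649), with a range of 2.71e-05 to 0.256. The fibroblast set call ended with normexp (0.096), with spike-in scaling (0.219) and without control replicate 2 (0.0587), with a range of 2.84e-04 to 0.419. Extracellular matrix genes, of which 6 are also fibroblast markers, had 3 risers, 25 fallers and 9 uncalled (3 and 25 adjusted over the list alone). The matrix median was -0.34, -0.42 with slide as a block and 0.09 with spike-in scaling (adjusted p = 0.00138, and adjusted p = 0.364 with an estimated correlation). Elastin Eln fell by 0.88, periostin Postn by 0.81 and collagen Col3a1 by 0.60, and in the processed signal the matrix protease Mmp9 was at least 3.03-fold lower, with 0 of 3 arrays at 24 h above background (-0.71 with normexp and -0.36 with the series matrix).

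The ion channel, calcium handling and cardiac transcription factor lists were lower at 24 h, and with spike-in scaling only the ion channel median was below 0. Ion channel and gap junction genes had 1 riser, 18 fallers and 9 uncalled (1 and 18 adjusted over the list alone). The ion channel median was -0.56, -0.44 with slide as a block (adjusted p = 9.29e-04, and adjusted p = 0.0693 with an estimated correlation). Kcnip2, a subunit of the channel of the transient outward potassium current, fell by 1.45 and the sodium channel subunit Scn4b by 1.41, while Kcne1, a subunit of a delayed rectifier potassium channel, was by the fit 2.98-fold higher, which is no bound, with 0 of 3 control arrays above background. With normexp Kcne1 changed by 0.03 and was not called (adjusted p = 0.857, range 2.01e-21 to 0.857), and with the series matrix it changed by 0.52. Calcium handling genes had 1 riser, 13 fallers and 7 uncalled (1 and 15 adjusted over the list alone). The calcium handling median was -0.31, -0.27 with slide as a block and 0.12 with spike-in scaling (adjusted p = 0.0289, and adjusted p = 0.152 with an estimated correlation). This call ended with normexp (median -0.19, adjusted p = 0.107) and with spike-in scaling (0.258), with a range of 2.49e-06 to 0.258. The histidine-rich calcium-binding protein Hrc fell by 1.09, Trdn by 0.59 and the calcium pump Atp2a2 by 0.57 (by 0.08 on its other probe), and Casq1, the skeletal-muscle calsequestrin, rose by 0.91. Cardiac transcription factors had 0 risers, 13 fallers and 8 uncalled (0 and 13 adjusted over the list alone). The transcription factor median was -0.30, -0.28 with slide as a block and 0.13 with spike-in scaling (adjusted p = 0.00569, and adjusted p = 0.172 with an estimated correlation), with Irx4, a ventricular homeobox factor, at -1.17 and Mef2c at -0.58. With spike-in scaling the transcription factor list did not pass (adjusted p = 0.0738, range 3.63e-06 to 0.172). The myosin heavy chains Myh6 and Myh7 fell by 0.33 and 0.38, but with spike-in scaling they were 0.10 and 0.05 higher, and scaled by the array median Myh6 was not called (adjusted p = 0.106, range 4.18e-04 to 0.694). Sarcomere genes as a list had 2 risers and 11 fallers, also over the list alone, and did not pass (median -0.25, and 0.18 with spike-in scaling; adjusted p = 0.221), with titin Ttn at -0.64 and Myom2 at -0.68.

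Fatty-acid oxidation genes had 1 riser, 23 fallers and 7 uncalled at 24 h (2 and 23 adjusted over the list alone). The fatty-acid oxidation median was -0.32, -0.25 with slide as a block and 0.11 with spike-in scaling (adjusted p = 8.98e-05, and adjusted p = 0.364 with an estimated correlation). Hadh, an enzyme of mitochondrial beta-oxidation, fell by 0.94, Ppargc1a, a coactivator of mitochondrial biogenesis, by 0.79, and the lipid droplet protein Plin5 by 1.43 with 1 of 3 arrays at 24 h above background. Oxidative phosphorylation genes had 1 riser, 18 fallers and 12 uncalled (1 and 19 adjusted over the list alone). The oxidative phosphorylation median was -0.19, -0.16 with slide as a block, 0.24 with spike-in scaling and 0.00 with array medians (adjusted p = 0.00138, and adjusted p = 0.411 with an estimated correlation), with mitochondrial creatine kinase Ckmt2 at -0.75 and the cytochrome oxidase subunit Cox8b at -0.54. This set call ended with slide as a block (adjusted p = 0.0779), array medians (0.0716), normexp (0.109) and spike-in scaling (0.434), with a range of 1.72e-05 to 0.434.

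Ribosome biogenesis genes had 20 risers, 0 fallers and 3 uncalled at 24 h (22 and 0 adjusted over the list alone). The ribosome biogenesis median was 0.45, 0.38 with slide as a block (adjusted p = 1.38e-12, and adjusted p = 0.0693 with an estimated correlation), with Gnl3 at 0.67 and Bop1 at 0.55. Hypertrophy and stretch markers had 18 risers, 3 fallers and 2 uncalled (18 and 3 adjusted over the list alone). The hypertrophy median was 0.51, 0.52 with slide as a block (adjusted p = 3.83e-10, and adjusted p = 0.0693 with an estimated correlation). Xirp2 rose by 1.55, Tnfrsf12a by 1.30, the actin regulator Enah by 1.27, Rcan1 by 1.07, Acta1 by 0.32, Ankrd1 by 0.32 and, from the YAP/TAZ list, Ccn2 by 0.48. Immediate-early genes had 16 risers, 3 fallers and 8 uncalled (17 and 3 adjusted over the list alone). The immediate-early median was 0.28, 0.34 with slide as a block (adjusted p = 2.86e-07, and adjusted p = 0.128 with an estimated correlation), with Atf3 at 1.56, Fosl1 at 1.46 and the growth regulator Myc at 1.07. Fos (0.26, adjusted p = 0.0709) and Egr1 (0.22, adjusted p = 0.114) were not called, but gained a call under 6 and 4 of 25 alternatives. NRF2 and oxidative-stress genes had 11 risers, 2 fallers and 10 uncalled (11 and 2 adjusted over the list alone). The NRF2 median was 0.20, 0.33 with slide as a block (adjusted p = 4.76e-04, and adjusted p = 0.364 with an estimated correlation), and Hmox1 rose 2.67-fold (1.42 ± 0.13) and Srxn1 by 1.18.

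Cholesterol synthesis genes, lower at the earlier times except with spike-in scaling, had 13 risers, 1 faller and 8 uncalled at 24 h (13 and 1 adjusted over the list alone). The cholesterol median was 0.19, 0.16 with slide as a block (adjusted p = 1.89e-05, and adjusted p = 0.0693 with an estimated correlation). Idi1, an enzyme of isoprenoid synthesis, rose by 0.53 and squalene epoxidase Sqle by 0.40. Heat-shock and chaperone genes had 13 risers, 0 fallers and 8 uncalled (14 and 0 adjusted over the list alone). The heat-shock median was 0.20, 0.14 with slide as a block (adjusted p = 5.12e-07, and adjusted p = 0.214 with an estimated correlation); Hspa4l rose by 0.81 and Bag3 by 0.50. The p53 and apoptosis list had 12 risers, 5 fallers and 6 uncalled (14 and 6 adjusted over the list alone). The p53 median was 0.20, 0.27 with slide as a block (adjusted p = 0.00204, and adjusted p = 0.0693 with an estimated correlation), with the kinase Plk2 at 1.30, the nuclease Aen at 0.70 and Sesn1 at -0.62. The unfolded protein and integrated stress response list had 10 risers, 4 fallers and 16 uncalled (10 and 4 adjusted over the list alone). The unfolded protein median was 0.03, -0.04 with slide as a block (adjusted p = 0.0053, and adjusted p = 0.364 with an estimated correlation), with Mthfd2, a mitochondrial folate enzyme, at 0.66. This set call ended with slide as a block (adjusted p = 0.16) and with quantile normalization (0.0546), with a range of 3.91e-04 to 0.364. Among genes outside the lists Rnd1, a small GTPase that acts on the actin cytoskeleton, rose by 1.80, the protease-activated receptor gene F2rl1 by 1.68 and Duox2 by 1.84; with normexp F2rl1 rose by 0.62 and Duox2 by 0.87. In the processed signal the transcription factor Foxa2 was at least 4.29-fold higher, with 0 of 3 control arrays above background, but it changed by 0.66 with the series matrix and by 0.21 with normexp, where it was not called (adjusted p = 0.155, range 1.47e-38 to 0.155).

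The 24 h calls came from limma and rest on arrays of slide 2 against controls on slide 1. With slide as a block 2045 genes were called, 497 higher and 1548 lower, 2008 of them among the 6888, and 65 of 73 called named genes and 15 of 18 lists kept their calls. The named genes that did not were Myh6 (-0.18, adjusted p = 0.347), Myh7 (-0.35, 0.0827), Ankrd1 (0.24, 0.173), Ccn2 (0.35, 0.0649), Hspa4l (0.64, 0.0543), Trdn (-0.42, 0.115), Flt1 (-0.56, 0.0798) and Ttn (-0.46, 0.125), each with its sign kept; over their alternatives the adjusted p of these 8 reached as low as 2.29e-08 and as high as 0.854. Hspa4l also lost its call with normexp (0.17, adjusted p = 0.145). With the series matrix Plin5 changed by -0.49 and Cdh5 by -0.30. With spike-in scaling the calls of Eln (-0.45, adjusted p = 0.0583), Postn (-0.38, 0.11), Col3a1 (-0.16, 0.497), Thy1 (-0.36, 0.127), Cdh5 (-0.21, 0.374) and Flt1 (-0.34, 0.154) ended. So did those of Atp2a2 (-0.14, 0.57), Trdn (-0.16, 0.522), Mef2c (-0.15, 0.55), Ttn (-0.21, 0.385), Myom2 (-0.25, 0.284), Cox8b (-0.10, 0.675), Ckmt2 (-0.32, 0.175), Ppargc1a (-0.36, 0.129) and Sesn1 (-0.19, 0.433), and of Myh6 (0.10, 0.694) and Myh7 (0.05, 0.854), which changed sign. Over the alternatives the adjusted p of these 17 reached as low as 3.3e-08 and as high as 0.854. Of the called genes 66.3% were lower, against 46.7% with quantile normalization (3338 higher and 2929 lower), 28.3% with array medians (5579 and 2202), 65.5% with normexp, 55.9% with the series matrix (2822 and 3577), 10.4% with spike-in scaling (4864 and 567) and 75.7% with slide as a block. List medians at 24 h also depended on the scaling. Over the same 4 scalings the medians lay between -0.43 and -0.20 for ion channels, -0.41 and -0.21 for endothelial markers, -0.27 and -0.10 for cardiac transcription factors, -0.31 and -0.15 for extracellular matrix, -0.29 and -0.12 for fatty-acid oxidation and -0.37 and -0.23 for interferon-stimulated genes, with -1.30 and -1.15 for macrophage markers. The groups did not overlap for 58.9% of genes, against 10% by chance.

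**Figure D3:**
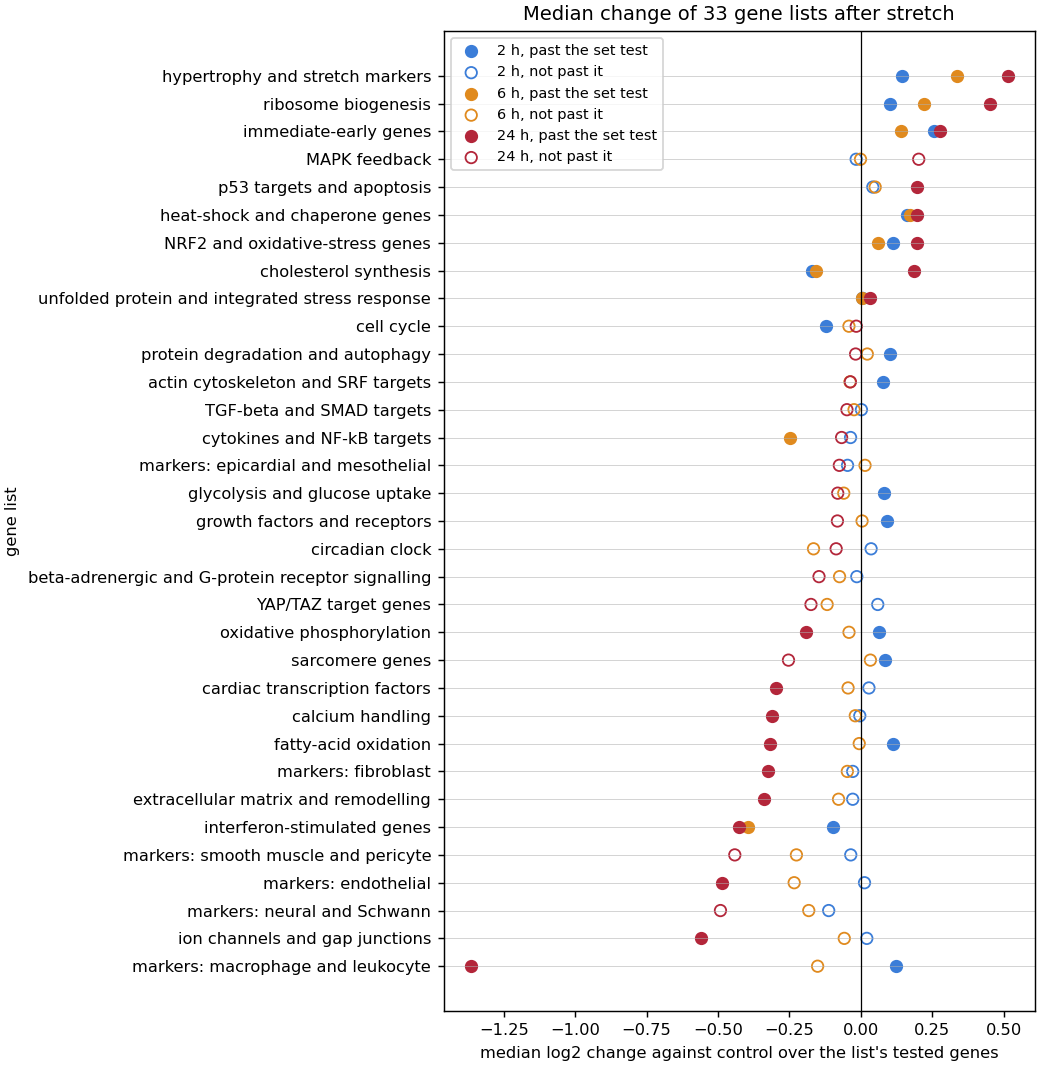
Median log2 change of each of 33 gene lists against the unstretched control at 2, 6 and 24 h of stretch; filled symbols passed the camera set test at an adjusted p below 0.05 and open symbols did not. The macrophage and leukocyte list was lowest at 24 h (-1.37), and cholesterol synthesis lay below 0 at 2 and 6 h and above 0 at 24 h; with spike-in scaling its medians at 2 and 6 h lay above 0.

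The last comparisons ask what changed between stretch times, or with time in culture. From 2 h to 6 h the inflammatory cytokine gene Il1a fell by 2.02, with 1 of 3 arrays at 6 h above background, the class II antigen gene RT1-Da by 1.34, with 2 of 3, and Duox2 rose by 0.90. Macrophage and leukocyte markers had 0 risers, 6 fallers and 6 uncalled from 2 h to 6 h (0 and 8 adjusted over the list alone). The macrophage median was -0.28, and 0.03 with spike-in scaling (adjusted p = 4.43e-05, and adjusted p = 0.376 with an estimated correlation). Interferon-stimulated genes had 0 risers, 9 fallers and 11 uncalled (1 and 11 adjusted over the list alone). The interferon median was -0.22, and 0.08 with spike-in scaling (adjusted p = 0.00319, and adjusted p = 0.376 with an estimated correlation). In all 1506 genes differed, 529 higher and 977 lower at 6 h. From 6 h to 24 h Stmn4 rose by 2.31, the chemokine gene Cxcl1 by 1.54, the mitochondrial creatine kinase gene Ckmt1 by 1.47 and Foxa2 by 1.79, with 1 of 3 arrays at 6 h above background. Adgre1 fell by 2.42 and Cd74 by 2.34, with 1 of 3 arrays at 24 h above background, and in the processed signal Gpr18 and RT1-Bb were at least 4.98-fold and 4.23-fold lower, with 0 of 3 arrays at 24 h above background. With normexp and the series matrix the changes were -0.94 and -0.88 for Gpr18, and -0.70 and -0.60 for RT1-Bb, and Cd74 changed by -1.04 with normexp.

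A group of 5 lists differed between 6 h and 24 h with a preset and with an estimated correlation. Cholesterol synthesis genes had 19 risers, 0 fallers and 3 uncalled from 6 h to 24 h (20 and 1 adjusted over the list alone). The cholesterol median was 0.40, 0.37 on slide 2 alone (adjusted p = 9.1e-15, and adjusted p = 0.00754 with an estimated correlation). All 12 macrophage and leukocyte markers fell (0 and 12 adjusted over the list alone). The macrophage median was -1.28 over all arrays and on slide 2 alone (adjusted p = 8.15e-15, and adjusted p = 0.018 with an estimated correlation). Ion channel genes had 1 riser, 15 fallers and 12 uncalled (1 and 15 adjusted over the list alone). The ion channel median was -0.36, -0.33 on slide 2 alone (adjusted p = 3.51e-05, and adjusted p = 0.0176 with an estimated correlation). Calcium handling genes had 1 riser, 11 fallers and 9 uncalled (1 and 13 adjusted over the list alone). The calcium handling median was -0.26 (adjusted p = 0.00193, and adjusted p = 0.0392 with an estimated correlation). Among p53 targets 10 rose, 2 fell and 11 were not called (11 and 2 adjusted over the list alone). The p53 median was 0.16 (adjusted p = 7.23e-04, and adjusted p = 0.0347 with an estimated correlation). In all 3601 genes differed between 6 h and 24 h, 1376 higher and 2225 lower at 24 h, and 6927 between 2 h and 24 h, 2584 higher and 4343 lower.

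These differences came from limma. From 2 h to 6 h the count was 599 with slide as a block, 238 on slide 1 alone, 556 without 2 h replicate 1, 924 without 2 h replicate 2, 345 without 6 h replicate 1, 814 without 6 h replicate 2 and 599 without 6 h replicate 3; RT1-Da was not called on slide 1 alone (-1.28, adjusted p = 0.0525) or with normexp (-0.41, 0.134), with a range of 5e-05 to 0.134. Duox2 was not called with normexp (0.43, adjusted p = 0.103, range 1.16e-06 to 0.103), and Il1a changed by -0.61 with normexp and -0.64 with the series matrix. From 6 h to 24 h it was 1101 with slide as a block and 240 on slide 2 alone, which holds 1 array of 6 h; there Foxa2 (1.35, adjusted p = 0.0755), Cxcl1 (1.35, 0.158) and RT1-Bb (-2.65, 0.118) kept their sign but were not called, and their ranges ended at those values and began at 6.85e-16, 9.06e-12 and 1.42e-35. With normexp Foxa2 was not called either (0.35, adjusted p = 0.0584), and with the series matrix it changed by 0.54. From 2 h to 24 h it was 1805 with slide as a block. The share that was lower, of the called genes, was 64.9%, 61.8% and 62.7% for the 3 differences, 39.7%, 46.3% and 42.0% with quantile normalization, 30.2%, 30.2% and 31.0% with array medians, 47.4%, 62.4% and 60.4% with normexp, 47.4%, 53.3% and 51.5% with the series matrix, and 5.34%, 86.0% and 30.1% with spike-in scaling.

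**Figure D4:**
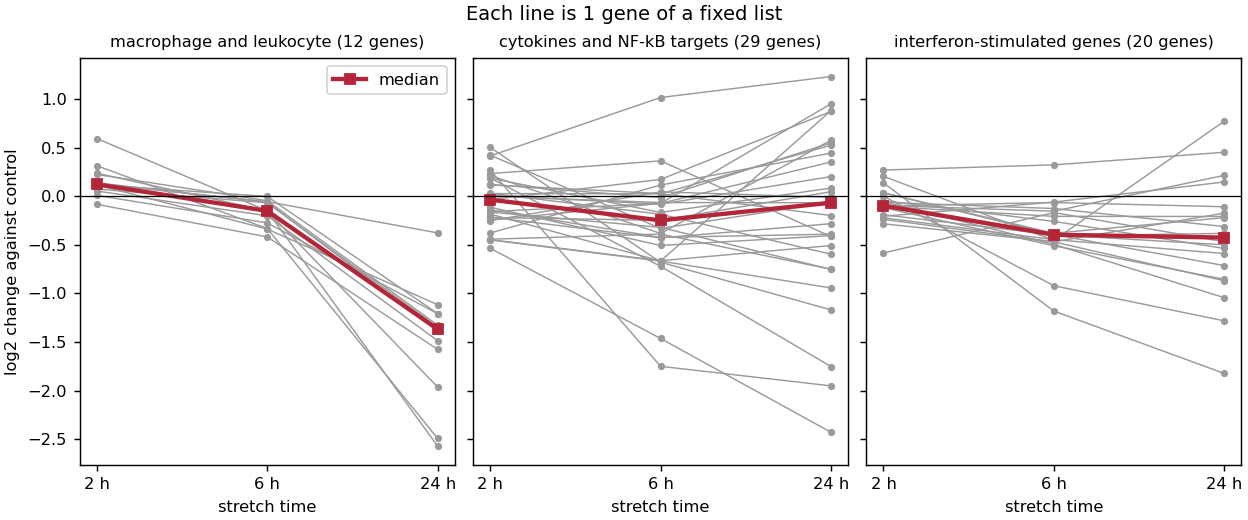
Log2 change against the unstretched control at 2, 6 and 24 h for 12 macrophage and leukocyte markers, 29 cytokines and NF-kB targets and 20 interferon-stimulated genes; thin lines are single genes and the red line is the median of the list. All 12 macrophage and leukocyte markers lay below 0 at 24 h, whereas cytokine genes went both ways; with spike-in scaling the medians of both other lists lay above 0 at all 3 times, as the cytokine median did at 2 and 24 h with array medians.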

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

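The tests of fewer macrophages, at 6 h and at 24 h, of the scaling of the arrays for the excess of falling genes, and of the probes without a gene name were chosen after the results they concern had been seen, as were spike-in scaling and the values between stretch times with slide as a block or under other scalings.

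Stretch times differed from each other, by limma's test of the difference itself at an adjusted p below 0.05, for 87 of 95 named genes and for 26 of 33 lists. The values are differences of log2 change, with n = 3 arrays per group.

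Each gene and list is given once, at the first difference it passed, in the order 24 h against 2 h, 24 h against 6 h and 6 h against 2 h. It may differ at a later one too. For 83 genes the difference given is 24 h minus 2 h. All 2 h arrays lay on slide 1 and all 24 h arrays on slide 2, so these differences cross slides. With slide as a block 59 of the 83 kept their call, 24 did not, and none changed sign. Those that did not included Nppb, Tnfrsf12a, Myh6, Ttn, Trdn, Fos, Atf3, Hbegf, Areg, Dnajb1, Hmox1, Srxn1, Heatr1, Kif11 and Dhcr7. The rest of the 24 were Spic, Gpr18, Cxcl1, Kcne1, Flt1, Thy1, Mef2c, Pmepa1 and Sesn1. For Hbegf the difference by limma was then 0.03 (adjusted p = 0.84). Among hypertrophy markers and contractile genes the difference over all arrays, without the block, was Nppb (0.54), Nppa (0.86), Rcan1 (0.63), Tnfrsf12a (0.54), Xirp2 (1.41), Enah (0.96) and Gdf15 (1.70). It was Myh6 (-0.47), Myh7 (-0.46), Ttn (-0.35), Myom2 (-0.69), Atp2a2 (-0.58), Hrc (-1.22), Trdn (-0.46) and Casq1 (1.05). Immediate-early and growth genes included Fos (-0.34), Atf3 (0.40), Fosl1 (0.86), Myc (0.60), Hbegf (0.15) and Areg (0.49). Chaperone and oxidative-stress genes included Hspa1b (-0.89), Dnajb1 (-0.37), Hspa4l (0.87), Hmox1 (0.68), Srxn1 (0.68) and Duox2 (1.75). Ribosome biogenesis and cell cycle genes included Heatr1 (0.27), Gnl3 (0.60), Bop1 (0.44) and Kif11 (0.37). For sterol genes the differences were Dhcr7 (0.34), Idi1 (0.71) and Sqle (0.51).

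Inflammatory and macrophage genes differed by large amounts: Tnf (-1.89), Il1b (-1.94), Ccl3 (-1.34), Usp18 (-1.28), Irf7 (-0.99), Il1rl1 (0.82) and Cxcl1 (1.06). Further differences of this kind were Adgre1 (-3.16), Ptprc (-1.49), C1qa (-2.80), Aif1 (-2.20) and Cd74 (-3.24). For Spic (-1.78), Il1a (-2.22), RT1-Bb (-3.76), RT1-Da (-3.51), Gpr18 (-3.61) and Mmp9 (-2.45) no array at 24 h was above background, nor any at 2 h for Spic, and for Foxa2 (2.19) and Kcne1 (0.87) at most 1 of 3 arrays at 2 h was, so these values are fitted differences and no bounds. Metabolic genes differed as follows: Plin5 (-1.75), Hadh (-0.96), Ppargc1a (-0.49), Ckmt2 (-0.92), Cox8b (-0.60), Ckmt1 (1.17), Pgam2 (-1.67), Aldoc (-1.39) and Mthfd2 (0.59). Channel genes and cardiac transcription factors gave Kcnip2 (-2.04), Scn4b (-1.28), Kcnq1 (-0.55), Irx4 (-0.67) and Mef2c (-0.31). In matrix, endothelial and fibroblast genes the differences were Eln (-0.99), Postn (-0.75), Col3a1 (-0.55), Thy1 (-0.53), Flt1 (-0.61) and Cdh5 (-0.70). The TGF-beta targets Smad7 (-0.50) and Pmepa1 (-0.55) and the p53 targets Plk2 (1.00), Aen (0.66) and Sesn1 (-0.34) also differed, as did Rnd1 (0.92), F2rl1 (1.27), Stmn4 (2.96) and Krt18 (0.81).

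Among genes not called between 24 h and 2 h, 3 differed between 24 h and 6 h, namely Acta1 (-0.29), Egr1 (0.37) and Skil (0.33). For 1 further gene, Ccn2, only the difference between 6 h and 2 h was called (-0.23). With slide as a block none of these 4 kept its call (adjusted p = 0.256, 0.111, 0.188 and 0.061).

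List medians differed as follows, by camera with the preset correlation, each list again at the first difference it passed. Counted without that order, 17 lists passed between 24 h and 2 h, 19 between 24 h and 6 h and 17 between 6 h and 2 h. The medians between 24 h and 2 h come first. They were 0.36 for cholesterol synthesis, 0.43 for hypertrophy and stretch markers, 0.31 for ribosome biogenesis, 0.17 for p53 targets, 0.17 for cell cycle, 0.17 for NRF2 and oxidative-stress genes, 0.16 for immediate-early genes and 0.023 for the unfolded protein and integrated stress response. They were -1.51 for macrophage and leukocyte markers, -0.52 for ion channels, -0.42 for endothelial markers, -0.41 for fatty-acid oxidation, -0.32 for cardiac transcription factors, -0.31 for extracellular matrix, -0.29 for sarcomere genes, -0.29 for calcium handling and -0.24 for oxidative phosphorylation, the last 0.01 with spike-in scaling. Between 24 h and 6 h the MAPK feedback list differed by 0.31, but by 0.05 with normexp and 0.19 with the series matrix, and fibroblast markers by -0.22. Between 6 h and 2 h the medians were -0.27 for smooth muscle and pericyte markers, -0.22 for interferon-stimulated genes, -0.20 for the circadian clock, -0.16 for cytokines, -0.15 for YAP/TAZ targets, -0.14 for glycolysis and -0.072 for the actin cytoskeleton, and with spike-in scaling each of these 7 was above 0. With slide as a block 15 of the 17 lists kept their call between 24 h and 2 h, all but cell cycle (0.08, adjusted p = 0.236) and the unfolded protein response (-0.04, 0.363). Of the lists given here for the other differences, 2 of 2 kept it between 24 h and 6 h. Between 6 h and 2 h 6 of the 7 given here did, all but the circadian clock (adjusted p = 0.061). For 6 of the 26 lists the median was more than 2 times smaller under quantile normalization, array medians, normexp or the series matrix. With an estimated correlation 7 of the 53 list tests between times kept their call, of 99 made; these were cholesterol synthesis, ion channels, macrophage markers, p53 targets and calcium handling between 24 h and 6 h, and cholesterol synthesis and ion channels between 24 h and 2 h.

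Of 2036 tested probes without a gene name, which no other comparison uses, 530 (26.0%) differed between 24 h and control, 100 higher and 430 lower, against 8 at 2 h and 34 at 6 h. Between 24 h and 2 h 738 differed.

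Macrophage and leukocyte markers fell at 24 h by a median of 1.37, all 12 of 12, among them C1qa (-2.49), above background on all 3 arrays at 24 h. Another scaling as the cause is argued against by the medians under quantile normalization, array medians, normexp and the series matrix, the highest of which was -1.15 and the lowest -1.30, and with spike-in scaling it was -0.93. A difference between slides is argued against by the change from 6 h to 24 h on slide 2 alone, -1.28, with 1 array at 6 h. With slide as a block the median was -1.40, which rests on the same 6 h array and is no separate evidence. Fewer macrophages in the stretched cultures may account for the pattern, since all 12 markers fell, but lower expression per cell or time in culture would do so too, and no value here separates them. Counting macrophages in stretched and unstretched cultures would.

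More genes fell than rose at 24 h, 66.3% of those called. With slide as a block, which rests on 1 array of 6 h, 75.7% fell. This does not decide on a slide difference. The choice of scaling could account for the excess, since the share ranged from 28.3% with array medians to 65.5% with normexp, and was 10.4% with spike-in scaling. Loss of signal near background also stays open: the share was 83.7% in the dimmest of 3 classes of 4792 genes, 64.1% in the middle and 50.1% in the brightest, which neither requires nor excludes it. A biological excess, by stretch or time in culture, was not separated from these.

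Cytokine and interferon-stimulated genes that fell at 6 h, 23 members, had a median of -0.47. The same members had -0.51 on slide 1 alone and -0.41 to -0.37 under 4 other scalings, and the 12 macrophage markers had -0.15 (SD 0.14), but the 23 were picked as falling on these arrays, so these values do not decide between explanations. Over all members the cytokine median was -0.25 (-0.29 on slide 1 alone, -0.24 to -0.14 under the 4 scalings) and the interferon median -0.40 (-0.43, and -0.34 to -0.20), and both lists passed the set test in each of these. With spike-in scaling, where the median of all genes at 6 h was 0.43, the 23 had a median of 0.01. Fewer macrophages, lower expression per cell and time in culture, for which no matched controls are described, were not separated.

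Other splits of the arrays were tested for each count of genes. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05: the real split was 1 of 10 with as many genes, at 1322 at 2 h, 2408 at 6 h, 6888 at 24 h, 3601 between 24 h and 6 h and 6927 between 24 h and 2 h, where the highest of the other splits gave 0, and at 1506 between 6 h and 2 h, where it gave 1. For the 4 groups together, 1 of 100 groupings, the real one, gave as many as 7597 genes, the highest other gave 3443, and chance is excluded. For the lists, 5 of 100 groupings gave as many as 43 past the test, the highest other gave 57, and chance is not excluded.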

How the results depend on the processing

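Spike-in scaling and, for the lists, array medians, normexp, the series matrix and slide 1 alone were chosen after the data had been seen. The cause of a change was not tested unless said. Of the 154 named gene values, 141 were called and 94 of these kept their call and direction under every alternative that gave a value. Of 3911 alternative values 3816 kept both, 77 lost the call, 14 gained one and 4 reversed. Calls kept throughout numbered 15 of 26 at 2 h, 22 of 31 at 6 h and 51 of 73 at 24 h, and 22, 28 and 63 with spike-in scaling set aside. Some genes that the rule allows and whose call rested on 1 array were left out of the text after this was seen, so these shares describe the named genes alone. The reversed values were, with spike-in scaling, Dhcr7 at 0.014 and Ptprc at 0.064 at 6 h and Myh6 at 0.10 and Myh7 at 0.048 at 24 h, and, for the cytokine list at 24 h, a fall by fry where camera pointed up without passing (median -0.067). By construction spike-in scaling shifts all genes of an array alike: the spike-in level over the 75th percentile was 1.61 for control replicate 2 and 1.13 to 1.18 for the other controls, and lay between 0.74 and 1.61 over the arrays.

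Counts of called genes that moved by more than 1.5 times are these, in the order 2 h, 6 h, 24 h, 6 h against 2 h, 24 h against 6 h and 24 h against 2 h where all are given. A minimum change of 2-fold left 15, 30, 486, 20, 229 and 461. Spike-in scaling gave 173 at 2 h, 6692 at 6 h, 562 for 6 h against 2 h, 997 for 24 h against 6 h and 2554 for 24 h against 2 h. With slide as a fixed block the counts were 1600 at 6 h, 2045 at 24 h, 599 for 6 h against 2 h, 1101 for 24 h against 6 h, 1805 for 24 h against 2 h and 2798 over all groups. Slide 1 alone, with fewer arrays, gave 813 at 2 h, 1350 at 6 h, 238 for 6 h against 2 h and 1560 over its 3 groups, and slide 2 alone gave 240 for 24 h against 6 h and no value against control. Without a probe filter, which tests more genes, 644, 1385 and 442 were called at 2 h, at 6 h and for 6 h against 2 h. Normexp gave 839 at 2 h and 682 for 6 h against 2 h, and fitting only the groups compared gave 463 and 362. With 1 array left out the counts ranged from 665 to 1365 at 2 h (lowest without control replicate 2), from 1195 to 2536 at 6 h and from 345 to 1577 for 6 h against 2 h (both lowest without 6 h replicate 1), from 5773 to 7070 at 24 h, from 2402 to 3739 for 24 h against 6 h, from 5771 to 7046 for 24 h against 2 h, from 6432 to 7424 over all groups, and from 38 to 45 for lists. With an estimated correlation 0 of the 43 list calls by camera remained, against 59 called by fry.

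Replicate numbers did not pair the arrays: with group means removed, 18 pairs with the same number correlated at -0.11 to 0.10 across genes, pairs with other numbers at -0.14 to 0.17, and 3 of 12 arrays correlated best with their own number. With the numbers as a block 1030 genes were called at 2 h, 1139 for 6 h against 2 h and 6703 for 24 h against 2 h. Scan was not run apart from slide, and requiring all 12 arrays above background leaves some named genes without a value. Signal near background limits the dim genes: Kcne1, Foxa2 and Hspa4l at 24 h and Duox2 at 6 h lost their calls with normexp. Sizes depended on the background too: 21 of 141 called gene values were more than 2 times smaller with normexp and 18 of 140 with the series matrix, for instance Cd74 at 24 h (-1.33 and -1.22, against -2.80) and Il1a at 6 h (-0.59 and -0.48, against -1.75), and no other setting but spike-in scaling moved more than 2 values so far.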

Other observations

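Some list alternatives used here were, as said, chosen after the data had been seen. Of 28 growth factors and receptors 4 rose, 1 fell and 23 were not called at 2 h (4 and 2 adjusted over the list alone). The growth factor median was 0.09 (adjusted p = 0.0281, and adjusted p = 0.259 with an estimated correlation), and Hbegf, a ligand of the epidermal growth factor receptor, rose by 0.79 ± 0.05 at 2 h and 0.94 at 24 h, when Areg, another ligand of that receptor, rose by 1.12. The list's call at 2 h ended without control replicate 2 (adjusted p = 0.0555) or 2 h replicate 3 (0.0526), with normexp (median 0.02, 0.0765) and with no filter (0.327), with a range of 0.00247 to 0.327. At 24 h the list had 6 risers and 11 fallers, also when adjusted over the list alone, and did not pass (adjusted p = 0.627). Of 14 TGF-beta and SMAD targets 3 rose and 0 fell at 2 h (3 and 2 adjusted over the list alone), Smad7 by 0.70, Skil by 0.70 and Pmepa1 by 0.74, all 3 of them feedback inhibitors of the pathway, and the list did not pass (median 0.00, adjusted p = 0.135). At 24 h it had 3 risers and 5 fallers over all genes and over the list alone (adjusted p = 0.755). YAP/TAZ targets had 6 risers and 1 faller at 2 h (6 and 2 adjusted over the list alone, adjusted p = 0.08), among them Ccn2 at 0.56, and 5 risers and 10 fallers at 24 h (6 and 10 adjusted over the list alone, adjusted p = 0.762). MAPK feedback genes had 4 risers and 0 fallers at 2 h, also over the list alone (adjusted p = 0.15), and 7 and 5 at 24 h (8 and 5 adjusted over the list alone, adjusted p = 0.0537).

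Several lists passed the set test at 2 h with few called members. Ribosome biogenesis had 1 riser, 0 fallers and 22 uncalled (1 and 0 adjusted over the list alone). The ribosome biogenesis median was 0.10 (adjusted p = 4.76e-04, and adjusted p = 0.364 with an estimated correlation). Actin cytoskeleton had 2, 0 and 28 (2 and 0 adjusted over the list alone). The actin median was 0.08 (adjusted p = 0.00142, and adjusted p = 0.364 with an estimated correlation), a call that ended by fry (0.0574) and without control replicate 1 (0.0528, range 4.13e-05 to 0.364). Protein degradation and autophagy had 3, 1 and 19 (9 and 1 adjusted over the list alone). The protein degradation median was 0.10 (adjusted p = 0.00192, and adjusted p = 0.16 with an estimated correlation), a call that ended with quantile normalization (0.0639) and spike-in scaling (0.0662), with a range of 1e-04 to 0.16. Glycolysis had 1, 0 and 23 (4 and 0 adjusted over the list alone). The glycolysis median was 0.08 (adjusted p = 0.0053, and adjusted p = 0.364 with an estimated correlation), a call that ended with quantile normalization (median 0.02, 0.24), no filter (0.0757), the series matrix (0.0623) and spike-in scaling (0.0724), with a range of 0.00118 to 0.364. Oxidative phosphorylation had 0, 0 and 31 (0 and 0 adjusted over the list alone). The oxidative phosphorylation median was 0.06, and -0.00 with quantile normalization (adjusted p = 0.00684, and adjusted p = 0.487 with an estimated correlation), a call that ended with quantile normalization (0.981), no filter (0.122), spike-in scaling (0.118) and without 2 h replicate 1 (0.15, range 5.97e-05 to 0.981). By limma 2 of its 31 members had an unadjusted p under 0.05, and fry did not call the list (adjusted p = 0.176). Sarcomere genes had 1, 0 and 18 (1 and 0 adjusted over the list alone). The sarcomere median was 0.09 (adjusted p = 0.0224, and adjusted p = 0.379 with an estimated correlation), a call that ended with quantile normalization (0.405), no filter (0.185), the series matrix (0.0683) and spike-in scaling (0.127), by fry (0.0502), and without control replicate 1 (0.138) or 2 h replicate 1 (0.0781), with a range of 9.22e-04 to 0.405.

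Some lists that did not pass at 24 h held members with large changes. Glycolysis had 4 risers and 8 fallers, also over the list alone, with the muscle enzyme Pgam2 at -1.41 and Aldoc at -1.36. The glycolysis median was -0.08, and 0.11 with array medians, 0.00 with quantile normalization and 0.35 with spike-in scaling (adjusted p = 0.627). Epicardial and mesothelial markers had 4 and 3, also over the list alone (adjusted p = 0.482), with the keratin gene Krt18 at 1.18. Beta-adrenergic and G-protein receptor genes had 3 and 11, also over the list alone (median -0.15, but 0.05 with array medians and 0.29 with spike-in scaling, adjusted p = 0.215). Smooth muscle and pericyte markers had 3 and 6, also over the list alone (median -0.44, adjusted p = 0.527), and neural and Schwann markers 1 and 5 (1 and 6 adjusted over the list alone, median -0.49, adjusted p = 0.346), both below 0 under every scaling. Circadian clock genes had 5 and 5 (adjusted p = 0.788) and protein degradation genes 8 and 6 (adjusted p = 0.365), both also over the list alone. Cell cycle genes had 5 and 3 (2 and 1 adjusted over the list alone, adjusted p = 0.253) and actin cytoskeleton genes 6 and 10 (7 and 11 adjusted over the list alone, adjusted p = 0.893). The red blood cell list was not tested.

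Genes called at several times overlapped, but all 3 comparisons use the same 3 controls, which by itself gives agreement. Across genes, which are not independent replicates, the changes at 2 h and 6 h correlated at r = 0.55, at 2 h and 24 h at 0.22 and at 6 h and 24 h at 0.67, where 100 simulations of unchanged genes with shared controls gave 0.50. The covariances were 0.0239, 0.018 and 0.0583, against 0.00785 in the simulations. Both at 2 h and 6 h 251 genes were higher and 393 lower (22.5 and 102 for independent calls) and 6 went opposite ways. Both at 2 h and 24 h 265 were higher and 418 lower (71.9 and 278) and 120 went opposite ways, and both at 6 h and 24 h 614 were higher and 1373 lower (118 and 533) and 44 went opposite ways. At all 3 times 203 genes were higher and 294 lower. With 3 controls no split into separate controls was made, so how much of the excess over independent calls comes from the shared controls was not separated.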
